A study of Mus musculus with 2 samples.

How the data were processed

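Single-cell ATAC-seq measures which parts of the genome are open to the Tn5 transposase in single nuclei. GFP-positive cells of the mediobasal hypothalamus were sorted at postnatal day 8 and made into 1 control and 1 Nfia/b/x-deficient library with a droplet kit, per the labels. Per the labels' protocols, reads went through the Cell Ranger ATAC pipeline with default parameters. Per the submitters' processing notes, the build was mm10 and the tools were Cell Ranger 3.1, Signac 0.2.5, Seurat and MACS2, named without their roles. How regions were called, how cells were filtered and doublets treated, and how types were named is not given in the sources used here.

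The matrix the authors deposited lists which of 107377 regions was present in which of 22285 cells, as 112651747 entries, and is therefore presence or absence with no count of fragments. Each region was found in 81 to 18294 cells (median 496). The annotation the authors deposited gives each cell its library and 1 of 9 types. The matrix carries no cell names, so its cells were taken in the order of the annotation. This order was checked by assigning each cell to the nearest type profile built from other cells of its library: 80.8% of control and 76.2% of deficient cells got their own type, against 32.2% and 24.3% after shuffling the annotation within the library.

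The design written before the data were examined assumed counts per region and gene positions. With presence or absence, detections were summed over the cells of a type and library, since cells are not replicates, and divided by all detections of those cells. Presence saturates at 1 per cell, so a region open in most cells is understated. With 1 library per genotype no test between genotypes was made and no p-value is given. Shares of cells have exact Clopper-Pearson intervals, sums have exact Poisson intervals, and ratios have exact conditional binomial intervals, all at 95% and for counting error only. Log2 ratios of single regions used a pseudocount of 1 detection per 1000000 and regions with at least 50 detections over both libraries. They were computed in all tanycytes (alpha1, alpha2, beta1, beta2 and proliferating) and in each type with at least 100 cells in each library, which leaves out proliferating tanycytes. Counting error alone was simulated with Poisson draws from the pooled profile. By the rule fixed for regions without names, the 2 highest and 2 lowest regions with at least 200 detections are named by number. Comparisons of genes, gene lists, sequence motifs and the Nfia, Nfib and Nfix loci were not run, because the files do not pair region numbers with positions.

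The region sets were devised after it was seen that the regions have no names. For each type, up to 500 regions with the highest log2 ratio to all other cells were taken from a random part of the control cells (of the deficient cells for proliferating tanycytes). A region needed at least 20 detections in the type and a log2 ratio of at least 0.5. The remaining cells measured the sets. A first look used a pseudocount of 5 per 1000000 to choose the sets; the value of 1 was then taken from the design, and 5 was kept as an alternative. A set chosen for being specific in the control library tends to be less specific in any other library, so each set was also chosen in the deficient library. Both choices shared from 30 regions (tanycyte) to 217 regions (beta2), with 57 for astrocyte, 61 for alpha2 and 65 for ependymal regions. The control library gave 8 regions for proliferating tanycytes, too few to use. The ependymal set held 346 regions, of which 68.8% kept their direction in the other library, and its ratio was -0.03 in all tanycytes and 0.01 in ependymal cells, or -0.16 and 0.033 when chosen in the deficient library. The last sets were the 500 lowest and 500 highest regions between the libraries in alpha2 tanycytes, among regions with at least 200 detections in the alpha2 cells used for the choice. Ratios were placed among 10000 random lists matched in 50 bins of accessibility. Depth was matched by drawing equal numbers of cells per library in 20 bins of detections per cell.

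Region ratios were tested on simulated data for all tanycytes with 107377 regions, 50 regions per fold size. Simulated log2 changes of 1, -1, 2 and -2 were recovered as 0.89, -0.80, 1.88 and -1.48 with the pseudocount, which shrinks regions of low accessibility, and as 1.02, -0.96, 1.99 and -2.05 without it. No unchanged region (0%) reached 2-fold. Of 200 random region lists with no change, 5.5% fell outside the central 95% of their matched lists. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used. Alternatives were median-of-ratios and trimmed-mean scaling, other minimums and pseudocounts, cells thinned to 2000 detections (which left out 506 control and 848 deficient tanycytes), deeper cells only, the deepest 5% of cells left out, and reassigned cell types.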

Results

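Tanycytes are radial glia-like cells that line the third ventricle of the hypothalamus. Chromatin accessibility was profiled by single-cell ATAC-seq in cells sorted for a nuclear GFP tag that Rax-CreER switches on in tanycytes and leaves in their progeny. The cells came from the mediobasal hypothalamus of mice at postnatal day 8. One library came from control mice and 1 from mice in which the genes for the transcription factors NFIA, NFIB and NFIX were floxed, so each genotype had 1 library and no replicate. The comparison addresses what loss of these 3 factors does to the capacity of tanycytes to form neurons. The control library held 8948 cells and 50973118 detections, where a detection is a region found accessible in a cell, with a median of 4549.5 detections per cell. The Nfia/b/x-deficient library held 13337 cells and 61678629 detections, with a median of 4042 per cell. All 107377 regions were detected in both libraries. Intervals below are exact 95% intervals for counting error only. Those of detections treat each detection as independent and leave out variation between cells of a type, so they are too narrow where cells differ. Variation between animals could not be measured. The regions carry numbers and the files do not pair these with genes or positions, so accessibility at the deleted genes was not analysed here and each genotype rests on its label.

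Neurons and proliferating tanycytes took larger shares of the deficient library, and alpha2 tanycytes, beta2 tanycytes, astrocytes and oligodendrocyte precursor cells (OPCs) took smaller ones. Neurons made up 9.86% of control cells (882 cells, interval 9.25 to 10.5%) and 18.9% of deficient cells (2520 cells, 18.2 to 19.6%), a ratio of 1.92 (1.77 to 2.07). There were 12.1 neurons per 100 tanycytes in the control library and 25.1 in the deficient library. Proliferating tanycytes made up 0.704% of control cells (63 cells, 0.541 to 0.900%) and 7.75% of deficient cells (1033 cells, 7.30 to 8.21%), a ratio of 11.0 (8.53 to 14.4). Astrocytes were 3.63% of control and 1.67% of deficient cells, a ratio of 0.460 (0.386 to 0.548), and OPCs were 3.40% and 2.05%, a ratio of 0.605 (0.512 to 0.714). Ependymal cells, the ciliated cells of the ventricle wall, were 1.49% and 1.99%, a ratio of 1.34 (1.08 to 1.66), but among cells with at least 2000 detections the interval of their log2 ratio included 0 (0.29, -0.025 to 0.61). These shares use the authors' cell type names, and the sort sets which cells could enter them.

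**Figure D1:**
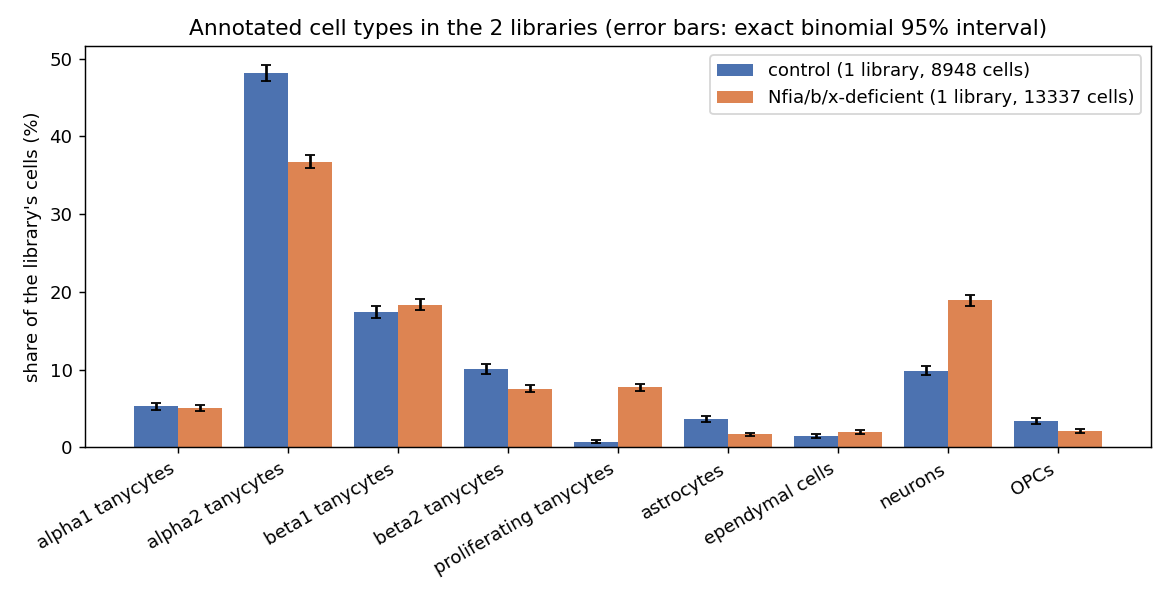
Share of each library's cells (percent, y axis) in each annotated cell type (x axis) for the control and the Nfia/b/x-deficient library; error bars are exact binomial 95% intervals for counting error. Neurons went from 9.86% to 18.9% and proliferating tanycytes from 0.704% to 7.75%, while alpha2 tanycytes went from 48.1% to 36.8%.

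Tanycytes as a whole were 81.6% of control and 75.4% of deficient cells. Alpha2 tanycytes, a subtype of the ventricle wall, were 48.1% of control and 36.8% of deficient cells, a ratio of 0.764 (0.733 to 0.796). Beta2 tanycytes, which lie over the median eminence, were 10.1% and 7.52%, a ratio of 0.744 (0.680 to 0.815). The shares of alpha1 tanycytes (ratio 0.949, 0.842 to 1.07) and beta1 tanycytes (1.05, 0.989 to 1.12) differed by less than counting error. Among tanycytes alone, alpha2 cells were 59.0% in the control and 48.8% in the deficient library, and beta1 cells were 21.3% and 24.3%. The class of proliferating tanycytes came almost entirely from the deficient library, and a class drawn mostly from 1 library may be a trait of that library. When each cell was assigned to the nearest of 9 type profiles built from other cells of both libraries, 2677 deficient cells and 0 of 8948 control cells fell in this class. The profile of this class was built almost wholly from deficient cells (1033 in the class, against 63 control cells). Any difference between the libraries would therefore draw deficient cells to it and keep control cells out. With profiles of control cells alone, 0% of control proliferating cells were assigned to the class, but neither was any deficient cell. That profile was built from few cells, so this cannot show whether control cells match the class. Under profiles of both libraries, limited by the mostly deficient profile of this class, beta1 tanycytes had a log2 ratio of -0.32 in place of 0.076. Alpha1 tanycytes had -1.18 in place of -0.076 and ependymal cells 0.90 in place of 0.42.

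Among single regions that differed by 2-fold or more in all tanycytes together, more were lower than higher in the deficient library. The median region was slightly higher when scaled by all detections. Of 107235 regions with at least 50 detections, 2.46% were lower by 2-fold or more and 0.999% were higher by 2-fold or more, while a simulation with counting error alone gave 0%. The median log2 ratio of deficient over control was 0.069, and the 5th and 95th percentiles were -0.77 and 0.68. The region with the highest ratio, region 43464, was detected in 54 control and 1210 deficient tanycytes, or 1.25 (0.938 to 1.63) and 25.02 (23.6 to 26.5) detections per 1000000 (log2 ratio 3.53). It was higher in all 9 cell types of the deficient library, where it ranged from 14.5 to 30.0 per 1000000. The next highest, region 43694, was detected in 173 control and 1168 deficient tanycytes (log2 ratio 2.33) and was also higher in all 9 types. The lowest ratio was that of region 8307, detected in 1765 control and 287 deficient tanycytes, or 40.8 (38.9 to 42.8) and 5.93 (5.27 to 6.66) per 1000000 (log2 ratio -2.59). Region 77982 followed, with 511 control and 75 deficient tanycytes (log2 ratio -2.33). Both of these regions were lower in all 9 types of the deficient library, with few detections in the smaller types. The differences of the named regions were thus not particular to tanycytes. With a pseudocount of 5 per 1000000 in place of 1, 0.0326% of regions were higher and 0.366% were lower by 2-fold or more. With tanycyte subtypes weighted equally 2.05% were higher and 2.74% lower. That weighting gives the 63 control proliferating cells as much weight as any other subtype, and counting error was not simulated for it.

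Within neurons, 11.6% of 62373 regions differed by 2-fold or more between the libraries, where counting error alone gave 0.205%. Of all regions tested in neurons, 6.03% were higher and 5.61% lower in the deficient library. Higher regions were 51.8% of those past 2-fold, 46.6% with median-of-ratios scaling and 69.7% with cells thinned to 2000 detections, so neither direction prevailed under every choice. The shares in tanycytes were 4.90% in alpha1, 4.11% in alpha2, 3.92% in beta1 and 3.91% in beta2 cells, against at most 0.239% from counting error. In alpha2 cells 1.15% of regions were higher and 2.97% lower. OPCs had 1.10% against 0.405% from counting error and astrocytes 0.636% against 0.386%. In ependymal cells the share was 0.407% against 0.498%, so the share of single regions past 2-fold did not exceed that from counting error. In beta1 tanycytes 40.9% of the regions past 2-fold were higher in the deficient library, 28.2% with median-of-ratios scaling, 13.8% with a minimum 4 times higher and 51.1% with no minimum, so which direction prevailed depended on the minimum. In OPCs the share was 29.0%, and 16.9% with median-of-ratios scaling. In types other than alpha2 the shares of regions past 2-fold fell with a higher minimum of detections, to 3.31% in neurons and 0.180% in alpha1 tanycytes at 4 times the minimum, where alpha2 tanycytes had 4.92%, so types of different depth cannot be ranked.

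To follow cell identity without gene names, sets of up to 500 regions were chosen as the most specific to each cell type in a random part of the control cells, and were measured in the remaining cells of both libraries. Regions specific to neurons were more accessible in deficient tanycytes: they took 0.534 of every 1000 detections in control and 0.764 in deficient tanycytes, a log2 ratio of 0.52 (0.48 to 0.55). The ratio was above 0 in all 8 non-neuronal types, from 0.34 in astrocytes to 0.65 in beta1 tanycytes. It was 0.46 in alpha2, 0.58 in beta2, 0.37 in alpha1 tanycytes and 0.40 in OPCs. In depth-matched cells it stayed above 0 in these types, but their order changed. Ependymal cells then had 0.86, astrocytes 0.81 and beta1 tanycytes 0.66. Proliferating tanycytes had 0.27, within depth-matched random lists (-0.19 to 0.46), from 31 cells per library. In neurons the direction was the opposite, with 8.40 per 1000 in the control and 4.40 in the deficient library (log2 ratio -0.93, -0.96 to -0.90). Over single neuron regions the median log2 ratio was 0.25 in all tanycytes and -1.01 in neurons; alpha1 tanycytes, astrocytes, ependymal cells and OPCs had too few detections per region for such a median. In all tanycytes the value for the set exceeded each of 10000 random lists matched on accessibility, whose central 95% ran from -0.01 to 0.12. When the set was chosen in the deficient library instead, which shared 202 of its 500 regions, the log2 ratio was 0.73 in all tanycytes, above 0 in the same 8 types, and -0.16 (-0.19 to -0.13) in neurons. A 4 times higher minimum of detections gave sets that were less specific (median log2 ratio to other cells 0.73 in place of 3.20) and ratios of 0.12 in tanycytes and -0.16 in neurons. In neurons the central 95% of random lists matched to the first set ran from -0.23 to -0.0096. The value of -0.93 lay below this range and both values of -0.16 within it.

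Regions specific to proliferating tanycytes, chosen in the deficient library because the control library had 63 such cells, were more accessible in all 9 types of the deficient library. In all tanycytes they took 2.22 of every 1000 detections in the control and 3.54 in the deficient library (log2 ratio 0.67, 0.66 to 0.69). This pool held 63 proliferating cells in the control and 1033 in the deficient library, and its ratio exceeded that of every non-proliferating tanycyte subtype. The ratio in proliferating tanycytes themselves (1.01) was favoured by the choice of regions in the deficient cells of this class. Of the other types, neurons had the highest ratio (0.72), followed by alpha1 and alpha2 tanycytes (both 0.60), beta1 (0.57) and beta2 tanycytes (0.50). OPCs (0.28), astrocytes (0.23) and ependymal cells (0.16) had smaller ones. Of these regions 56.6% had the same direction in the control library's proliferating cells. A region with no detection there counts as the opposite direction. The remaining control cells of this class had 399 detections in these 500 regions, too few to follow single regions. A 4 times higher minimum of detections gave 0.27 in all tanycytes. In the control library the proliferating regions took 2.93 of every 1000 detections in proliferating tanycytes, below OPCs (3.44) and astrocytes (3.21). The control library gave too few regions for a reverse choice, so the rises in the other types could not be checked that way.

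**Figure D2:**
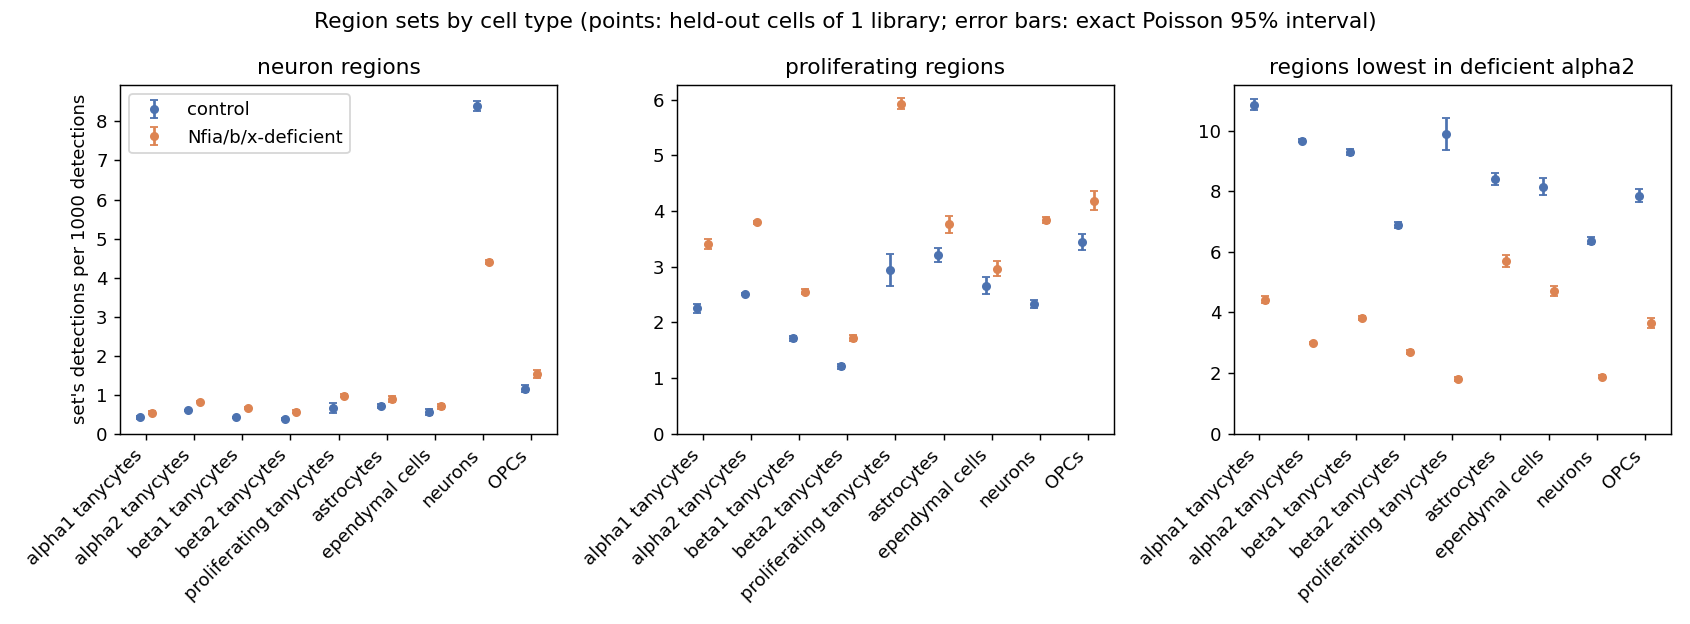
Share of detections (per 1000, y axis) that fell in neuron regions, in proliferating regions and in the regions lowest in deficient alpha2 tanycytes, by annotated cell type (x axis); each point is the held-out cells of 1 library and error bars are exact Poisson 95% intervals for counting error. Neuron regions were at 8.40 in control and 4.40 in deficient neurons, and were higher in the deficient library in the 8 other types.

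Regions specific to tanycytes were slightly less accessible in deficient tanycytes, at 2.85 per 1000 detections in the control and 2.60 in the deficient library (log2 ratio -0.13, -0.15 to -0.12). The ratio was lowest in proliferating tanycytes (-0.37), where the measured control cells had 321 detections in these 500 regions, too few to follow single regions. It was -0.13 in both beta1 and beta2 tanycytes, -0.11 in alpha1 and -0.094 in alpha2 tanycytes. Tanycyte regions chosen in the deficient library shared only 30 of 500 regions with this set, so they were mostly other regions. With them the ratio was -0.045 in beta1 and -0.060 in both beta2 and alpha2 tanycytes. The interval in alpha1 tanycytes included 0 (0.030, -0.025 to 0.084). In alpha2 cells matched on depth the ratio was 0.00. Neurons had a ratio of 0.12 with tanycyte regions chosen in the control library and -0.13 with those chosen in the deficient library. Regions specific to alpha1 tanycytes had a ratio of -0.34 in alpha1 cells, or -0.15 when chosen in the deficient library, and regions specific to beta1 tanycytes had -0.21 in beta1 cells, or -0.30. Regions specific to beta2 tanycytes had -0.10 in beta2 cells, but 0.012 (-0.019 to 0.043) when chosen in the deficient library, so the fall was not seen under both choices. Beta1 regions were lowest in proliferating tanycytes (-0.73, with 298 control detections). Astrocyte regions had a ratio of -0.11 in tanycytes, or -0.24 when chosen in the deficient library and -0.061 in depth-matched cells, and of -0.11 in astrocytes, or -0.081 when chosen in the deficient library. OPC regions were at -0.059 in OPCs and -0.038 in tanycytes, both within the spread of random lists. When chosen in the deficient library they were at 0.0037 (-0.035 to 0.042) in OPCs and -0.28 in tanycytes, where depth matching of the first choice turned the sign (0.019).

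The regions that differed most in alpha2 tanycytes differed, as sets, in the same direction in every other type. The 500 regions lowest in the deficient library, chosen in a random part of the alpha2 cells, had a log2 ratio of -1.69 (-1.70 to -1.67) in the remaining alpha2 cells, at 9.67 and 3.00 per 1000 detections. They were lower in all 9 types. The ratio was -2.45 in proliferating tanycytes, -1.76 in neurons, -1.36 in beta2, -1.29 in alpha1 and -1.28 in beta1 tanycytes, -1.11 in OPCs, -0.79 in ependymal cells and -0.56 (-0.62 to -0.50) in astrocytes. The 500 highest regions were higher in all 9 types, from 0.50 in ependymal cells to 1.24 in proliferating tanycytes, with 1.05 in alpha2 tanycytes and 0.92 in neurons. Regions in these sets needed at least 200 detections in the alpha2 cells used for the choice. Neuron regions are scarce there: all 500 together had 8578 control and 10577 deficient detections in the remaining alpha2 cells. That no neuron region was in either set therefore says nothing about neuron regions. Of the highest, 22 were among the proliferating regions, and the overlap between random sets was not computed.

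**Figure D3:**
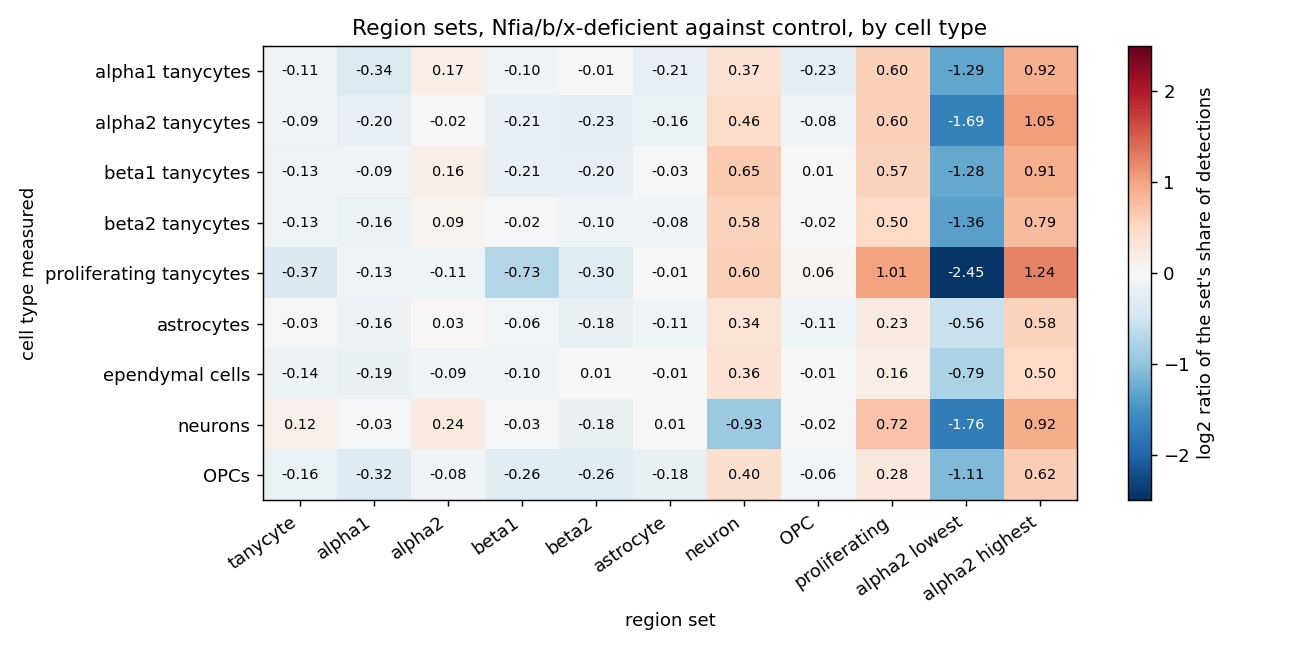
Log2 ratio of deficient over control (colour and number) of the share of detections in each region set (x axis) within each annotated cell type (y axis), measured in held-out cells of 1 library per genotype. The column of regions lowest in alpha2 tanycytes was below 0 in all 9 types, and the neuron column was above 0 in 8 types and -0.93 in neurons.

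At an equal depth of 900000 detections per type, and over 30019 regions found in at least 1000 cells, profiles of the same type in the 2 libraries were most alike in astrocytes (Pearson r = 0.841 across regions, which are not independent replicates), OPCs (0.833), ependymal cells (0.827) and beta2 tanycytes (0.825). They were less alike in alpha1 and beta1 tanycytes (both 0.783), neurons (0.773) and alpha2 tanycytes (0.748). Random parts of one type in one library, which could be compared for 5 types, gave 0.841 to 0.877. Deficient neurons resembled deficient proliferating tanycytes (r = 0.798), deficient alpha2 tanycytes (0.768) and deficient OPCs (0.767) about as closely as they resembled control neurons (0.773). This was not particular to neurons. Deficient alpha2 tanycytes had 0.823 with deficient proliferating and 0.748 with control alpha2 tanycytes. Deficient alpha1 tanycytes had 0.797 with deficient alpha2 and 0.783 with control alpha1 tanycytes. Deficient beta2 tanycytes, astrocytes, OPCs and ependymal cells were closest to their own type in the control library. Control neurons had r = 0.715 with control alpha2 tanycytes and 0.743 with control OPCs. Across libraries, deficient neurons and control alpha2 tanycytes had r = 0.623, and control neurons and deficient alpha2 tanycytes had 0.707.

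**Figure D4:**
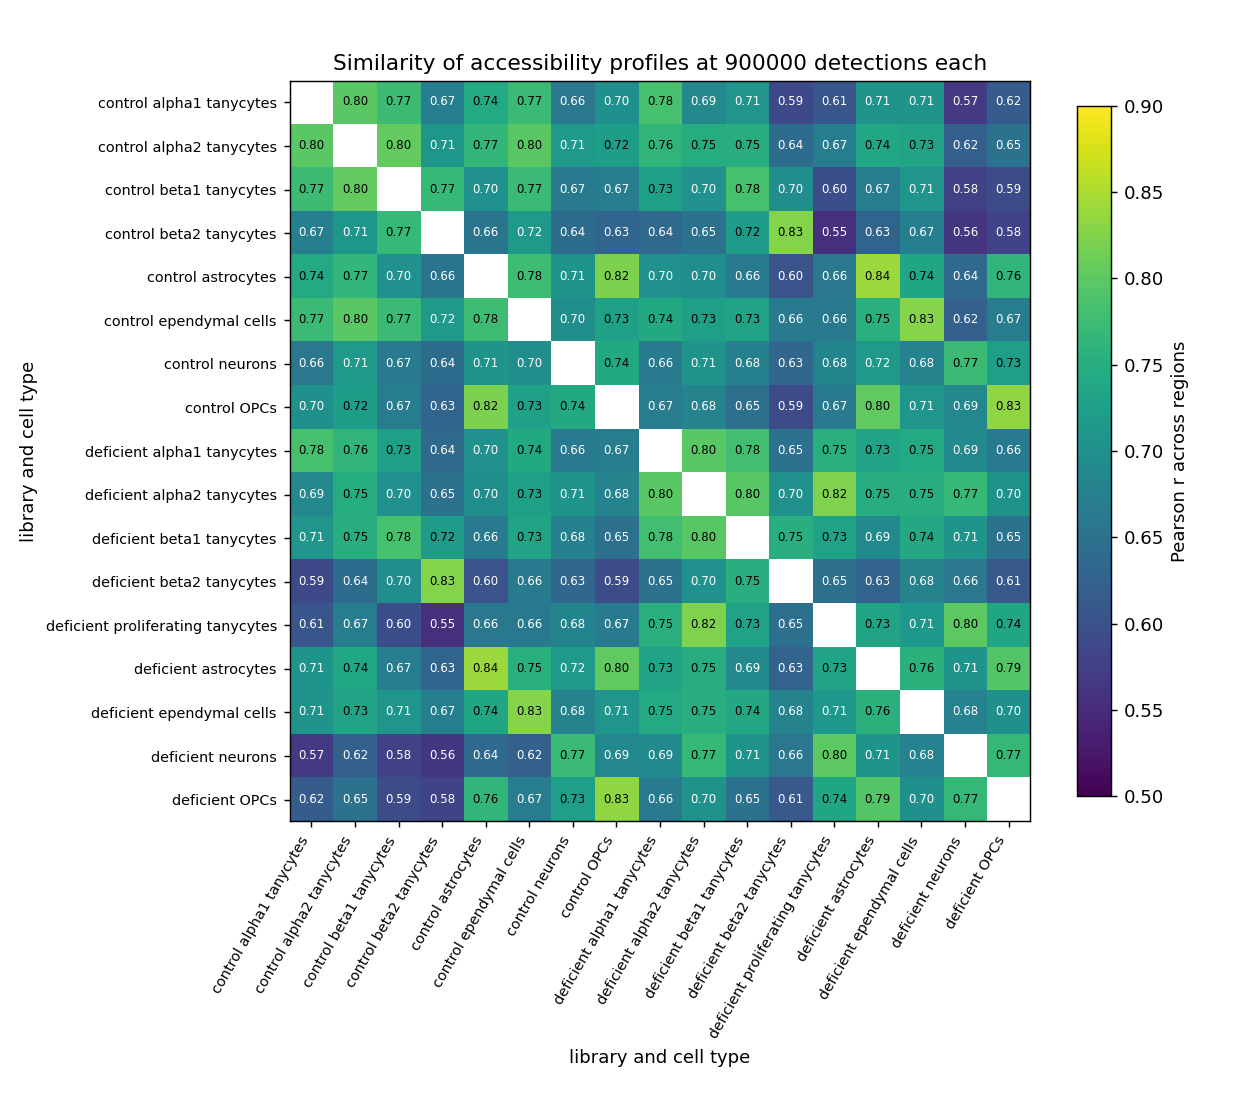
Pearson r across 30019 regions (colour and number) between accessibility profiles of each library and cell type (both axes), each reduced to 900000 detections; control proliferating tanycytes were too few to include. Deficient neurons had r = 0.798 with deficient proliferating tanycytes and 0.773 with control neurons. Deficient alpha2 tanycytes likewise had 0.823 with deficient proliferating tanycytes and 0.748 with control alpha2 tanycytes.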

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

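All tests in this part were chosen after the results were seen. Neuron regions had opposite directions in neurons and elsewhere: the log2 ratio of deficient over control was -0.93 in neurons and 0.34 to 0.65 in the 8 other types. The difference between types was not tested, because each genotype had 1 library.

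In neurons, the fall was smaller where the regions were chosen in the deficient library (-0.16, -0.19 to -0.13). The sign held under either choice, but each choice favours the library it was made in, so the size of the fall is not fixed. The central range of random lists in neurons, matched to the control-chosen set, ran from -0.23 to -0.0096. The value of -0.16 lay within it, as did the -0.16 from a 4 times higher minimum of detections. A fall particular to neuron regions was therefore not shown under these 2 choices. The values argue against tanycytes within the neuron class as the whole source of the fall of -0.93 seen with the control choice. An admixture of 52.3% would be needed, which predicts 1.98 tanycyte regions per 1000 detections in deficient neurons. The value found was 1.41 (1.37 to 1.44). The admixture needed for the fall of -0.16 was not computed, so tanycytes are not excluded as its source. Depth per cell does not account for the fall of -0.93, since depth-matched neurons had -1.01. A lower share of regions specific to control neurons may reflect younger neurons or another mix of neuron types under loss of the NFI factors, which was not tested, and library preparation stays open.

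In the 8 other types, choice of regions does not account for the rise, because regions chosen in the deficient library gave 0.73 (0.70 to 0.76) in all tanycytes. Free DNA with the library's average make-up would have to supply 27.1% of tanycyte detections, which predicts a log2 ratio of -0.29 for OPC regions in OPCs, and -0.059 (-0.099 to -0.019) was found. The prediction takes the same share of free DNA in OPCs as in tanycytes, and no free DNA in the control library. Neither was measured, so free DNA with a share that differs between types is not excluded. DNA of neurons alone, free or in doublets, could give the rise in tanycytes at 5.93% of their detections; this cannot be told apart from opening of neuronal regions in tanycytes, because the amount of such DNA was not measured and the deficient library held more neurons. A neuronal shift of tanycyte chromatin with the genotype stays open beside it.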

How the results depend on the processing

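The alternatives for region sets, depth matching and reassigned types were chosen after seeing the data; the others were planned before the data were examined. Of 128 alternative values, 61 stayed, 65 moved and 2 changed sign, where log2 ratios were held to the counting interval of the reported value and percents of regions to 1.5 times it; the cause was not tested unless stated. Log2 shares under reassigned types were -1.18 in alpha1, -0.63 in alpha2 and -0.32 in beta1 tanycytes, -1.45 in astrocytes, 0.90 in ependymal cells, 1.19 in neurons and -0.99 in OPCs. Proliferating tanycytes gave no ratio, with 0 control cells. Their profile came mostly from deficient cells, which limits all values under reassigned types. Neurons among cells with at least 2000 detections gave 1.15. Regions 2-fold higher in all tanycytes were 1.87% with thinned cells, 2.05% with subtypes weighted equally and 0.0326% with a pseudocount of 5 per 1000000, which gave 0.366% lower. Regions 2-fold lower were 2.81% with thinned cells and 2.74% with subtypes weighted equally. Either way within types, thinned cells gave 2.37% in alpha1, 6.25% in alpha2 and 2.21% in beta2 tanycytes and 1.12% in ependymal cells. No minimum gave 12.6% in alpha1 and 6.48% in beta2 tanycytes, 17.2% in astrocytes, 21.8% in ependymal cells and 21.0% in OPCs, where regions with few detections enter. A minimum 4 times higher gave 0.180% in alpha1, 1.63% in beta1 and 0.504% in beta2 tanycytes, 3.31% in neurons, and 0% in astrocytes (397 regions), ependymal cells (19) and OPCs (131). Median-of-ratios scaling moved the share of higher regions among those past 2-fold in all tanycytes from 28.9% to 18.9%. It sets the median of all regions to 0 by its definition, so the reported median of 0.07 depends on scaling by all detections.

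For region sets, log2 ratios in all tanycytes follow. Tanycyte regions gave -0.21 (median of ratios), -0.26 (pseudocount 5), -0.19 (minimum 4 times higher), -0.10 (thinned), -0.21 (parts of the cells swapped), -0.081 (chosen in the deficient library) and -0.16 (subtypes weighted equally). Neuron regions gave 0.44 (median of ratios), 0.45 (pseudocount 5), 0.12 (minimum 4 times higher), 0.56 (thinned), 0.72 (depth-matched), 0.47 (swapped) and 0.73 (chosen in the deficient library). In neurons they gave -0.97 (median of ratios), -0.76 (pseudocount 5), -0.16 (minimum 4 times higher), -1.01 (depth-matched) and -0.16 (chosen in the deficient library). Astrocyte regions gave -0.19 (median of ratios), -0.20 (minimum 4 times higher), -0.079 (thinned), -0.061 (depth-matched), -0.24 (chosen in the deficient library) and -0.10 (subtypes weighted equally). OPC regions changed sign when thinned (0.0035) and when depth-matched (0.019), and gave -0.11 (median of ratios), -0.023 (minimum 4 times higher), -0.062 (swapped), -0.28 (chosen in the deficient library) and -0.054 (subtypes weighted equally). Proliferating regions gave 0.60 (median of ratios), 0.58 (pseudocount 5), 0.27 (minimum 4 times higher), 0.69 (thinned), 0.72 (depth-matched), 0.71 (swapped) and 0.71 (subtypes weighted equally). A higher minimum removes regions of low accessibility and leaves sets that are less specific. The central 95% of random lists ran from -0.03 to 0.08 for tanycyte regions and from -0.082 to 0.0024 for OPC regions, whose reported ratio lay within it.

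Setting each entry to 0 or 1 was void because the matrix holds presence or absence, and leaving types outside the tanycyte lineage out of the denominator was not run because none of the 4 such types listed beforehand was annotated. Alternatives for genes, gene lists and motifs were not run because region numbers are not paired with positions. No paired analysis was possible because the groups share only replicate number 1.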

Other observations

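All tests of explanations in this part were chosen after the results were seen. The per-cell share of neuron regions was spread widely among control neurons. In cells thinned to 2000 detections, control neurons had a median of 7.5 per 1000 detections with quartiles of 3.5 and 14 (309 cells, 146 shallower ones left out). Deficient neurons had a median of 3.5 with quartiles of 2 and 6 (1006 cells, 299 left out). Without thinning the medians were 7.34 and 3.35. These regions were chosen in the control library, which favours control neurons; regions chosen in the deficient library gave a log2 ratio of -0.16 in held-out neurons, at 7.12 and 6.36 per 1000. For proliferating regions the thinned median in neurons was 2 in the control and 3.5 in the deficient library, and in alpha2 tanycytes it was 2.5 and 3.5.

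Regions specific to alpha2 tanycytes had log2 ratios of 0.17 in alpha1 tanycytes, 0.16 in beta1 tanycytes and 0.24 in neurons, and -0.02 in alpha2 tanycytes themselves. With the regions chosen in the deficient library these were 0.24, 0.20, 0.09 and 0.16. Not every type rose. Ependymal cells were at -0.092 with the control choice, with an interval that included 0, and at -0.20 (-0.31 to -0.081) with the deficient choice. OPCs (-0.082 and -0.12) and proliferating tanycytes (-0.11 and 0.065) had intervals that included 0 under either choice. Deficient cells of 4 types were nearest to alpha2 profiles more often than control ones under profiles of control cells, of deficient cells and of both: alpha1 tanycytes (75.8% against 39.1%, 43.3% against 7.61% and 32.0% against 13.3%), beta1 tanycytes (45.7% against 25.8%, 20.1% against 4.30% and 19.4% against 13.9%), astrocytes (39.9% against 32.9%, 45.3% against 24.9% and 29.1% against 19.7%) and, with smaller differences, beta2 tanycytes. OPCs were so less often under all 3. Ependymal cells had 56.6% against 78.2%, 32.8% against 29.3% and 25.7% against 42.1%, so their direction depended on the profiles. No counting intervals were computed for these percents, and the smaller differences may lie within counting error. Regions specific to alpha1 tanycytes were lower in the deficient library in 8 of 9 types under either choice; the exception, within counting error, was neurons (-0.03) with the control choice and astrocytes (-0.079) with the deficient choice.

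The larger class of proliferating tanycytes in the deficient library was weighed against technical sources. Doublets would raise the detections per cell. The median of this class (4503) was 0.982 times that of alpha2 tanycytes in the same library (4585). It was above the medians of beta2 (4049), alpha1 (3978) and beta1 tanycytes (3582.5). The outcome depends on the subtype compared, so doublets are not settled. The name may not cover one chromatin state in both libraries: regions that set the class apart from alpha2 tanycytes by a log2 ratio of 0.64 in deficient cells did so by 0.22 (0.078 to 0.37) in control cells. This cannot be told apart from the choice of the regions in the deficient library, because the control library gave 8 regions when the choice was reversed. The ratio of 11.0 between the shares is therefore a ratio of cells under one name. Library preparation and genotype cannot be told apart with 1 library per genotype, and whether more tanycytes divided was not tested.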
